A study of Mus musculus with 8 samples.

How the data were processed

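RNA was measured in 8 tumours that grew from TRAMP-C2 cells, an established mouse prostate adenocarcinoma line, in the prostate of male C57BL/6 hosts. Per the labels, 1 M cells were placed in each prostate, 19 aged hosts (20 to 24 months old) and 20 young hosts (4 months old) were injected, and tumours were taken 30 to 45 days later. 4 tumours of each age group were sequenced, and how these 4 were chosen, the day of harvest of each, its weight and any batch are not given in the sources used here. Per the labels, 1 µg of total RNA per tumour went into TruSeq mRNA libraries, which were read as 50 bp paired ends on an Illumina HiSeq. The design text names the stranded version of the kit.

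The submitters' processing notes name bcl2fastq, TopHat2 2.0.12 and Picard 2.7.1 and the mouse build GRCm38 (mm10). The counting program, its annotation and its strand setting are not given in the sources used here, so reads of genes that overlap each other, or of near-identical copies, may have been split or shared. Per the file headers, the deposited tables hold a fragment count for each of 24028 Entrez genes. The authors also deposited FPM values, which are CPM, since each is proportional to the count over the total of its tumour. The deposited FPKM values equal that CPM divided by the transcript length in the same table, and they were not used further. 27 gene symbols had turned into calendar dates and were restored through their Entrez numbers from a RefSeq table of GRCm38. The symbols of 5 genes were missing. The RefSeq table held 23968 of the Entrez numbers. Coordinates of named genes are those of that table, and overlaps were looked up in GENCODE vM21, which is on the same build.

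Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, scaled with TMM factors, and fitted with the robust quasi-likelihood model with host age as the only term. Fold changes are aged minus young on the log2 scale, with a standard error equal to the fold change divided by the square root of its F statistic. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and 0.05 was the threshold. Levels are log2 CPM with a prior count of 2. Tests were made on the 54 gene lists with limma 3.58.1 (camera, preset correlation 0.01, lists with at least 5 tested members). Each list was also tested with an estimated correlation, with fry, and by an exact permutation test of its mean log2 CPM per tumour, which has 70 assignments. Principal components used the 500 most variable genes. DESeq2 1.42.0, limma voom with sample weights, other scalings, filters and thresholds, a score of host gland transcripts and 1 surrogate variable (sva 3.50.0) as covariates, and each tumour left out in turn were the alternatives set before the data were examined. Exact permutation of list means, prior counts of 0.5 and 5, and the exclusion of 2 or 3 tumours with transcripts of other tissues were chosen after seeing the data.

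The named genes follow a rule set before the data were examined. It took up to 10 genes in each direction past the adjusted threshold with an average log2 CPM of at least 0 and no overlap between the groups, leaving out predicted models and antigen receptor segments. Where fewer than 5 passed in a direction, that direction was filled to 5 by the smallest p among genes meeting the level and separation criteria, and these are said not to pass. The rule added the 4 members with the smallest p of each list that passed, at most 2 of every other list, and 12 fixed genes. Genes outside the rule are said to be chosen after their values were seen.

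The whole procedure was tested on counts simulated from the means and library sizes of the 8 tumours (14416 genes). Of 100 genes changed 2-fold, 40 were recovered, and of 100 changed 4-fold, 88, with 11 false calls. Benjamini-Hochberg adjustment is stricter where few genes change, and many were changed together here. These rates thus do not say how many real changes the test could have missed. All 5 simulated lists of 15 genes shifted by 0.5 on the log2 scale were called, and 0 of 20 unshifted lists, although simulated genes vary independently of each other. Depth was 27.1 to 35.7 M fragments per tumour, at which 3 fragments are 0.084 to 0.111 CPM, a limit that covers counting error only. The lowest chi-square per degree of freedom between any pair of libraries was 44.8, so no library was a copy of another within sampling noise.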

Results

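The series profiled 8 tumours grown from TRAMP-C2 cells, a prostate adenocarcinoma line derived from a TRAMP transgenic mouse, in the prostate of male C57BL/6 hosts with working immune systems. 4 tumours came from aged hosts (20 to 24 months) and 4 from young hosts (4 months), and the labels give each tumour a mouse number of its own. Each tumour is named here by its host group and that number. The comparison asks how the transcriptome of the same tumour line differs when it grows in aged rather than young prostate. Bulk mRNA was counted, so transcripts of the injected cells and of the host cells within the tumour were measured together. The libraries held 27.1 M (young 37) to 35.7 M (young 43) fragments, and 17140 to 18418 genes had at least 1 fragment.

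The most abundant transcripts included a group of neighbours on chromosome 9, chosen after their values were seen. Yap1, a transcriptional coactivator of the Hippo pathway, ranked 2 of 14575 tested genes by median CPM. Tmem123, which encodes a transmembrane protein, ranked 5 and Dcun1d5, a cullin neddylation factor, ranked 7. Casp12, an inflammatory-type caspase, ranked 45, Cfap300 ranked 99 and Birc2, an inhibitor of apoptosis, ranked 110. Of the 100 most abundant genes, 5 started on chromosome 9 between 5345442 and 8042875 (GRCm38), while the next fullest stretch of 3 Mb held 3 (Rpl13a, Ftl1 and Ldha, on chromosome 7). This scan was chosen after a first scan, by the lowest median CPM of 10 consecutive tested genes, had placed 2 windows of the stretch at place 4 and place 13 of those that do not overlap. The flanking genes Msantd4 and Arhgap42 had median levels of 45.8 and 36.7 CPM. Not all genes within the stretch were high, as those of the Mmp family had medians of 0.307 CPM (Mmp20) to 121 CPM (Mmp3). Yap1 stood at 13400 CPM in aged 46 and 12200 CPM in aged 51, against 5440 to 7560 CPM in the other 6 tumours. Towards lower coordinates, Dcun1d5 stood at 1230 CPM in aged 46, against 3470 to 8090 CPM in the other 7 tumours, and Casp12 at 528 CPM, against 1300 to 2850 CPM. A set of 7 genes of the stretch, those above with Dync2h1, took 1.84% (aged 50) to 3.9% (aged 51) of all fragments. DNA copy number was not analysed here.

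**Figure D1:**
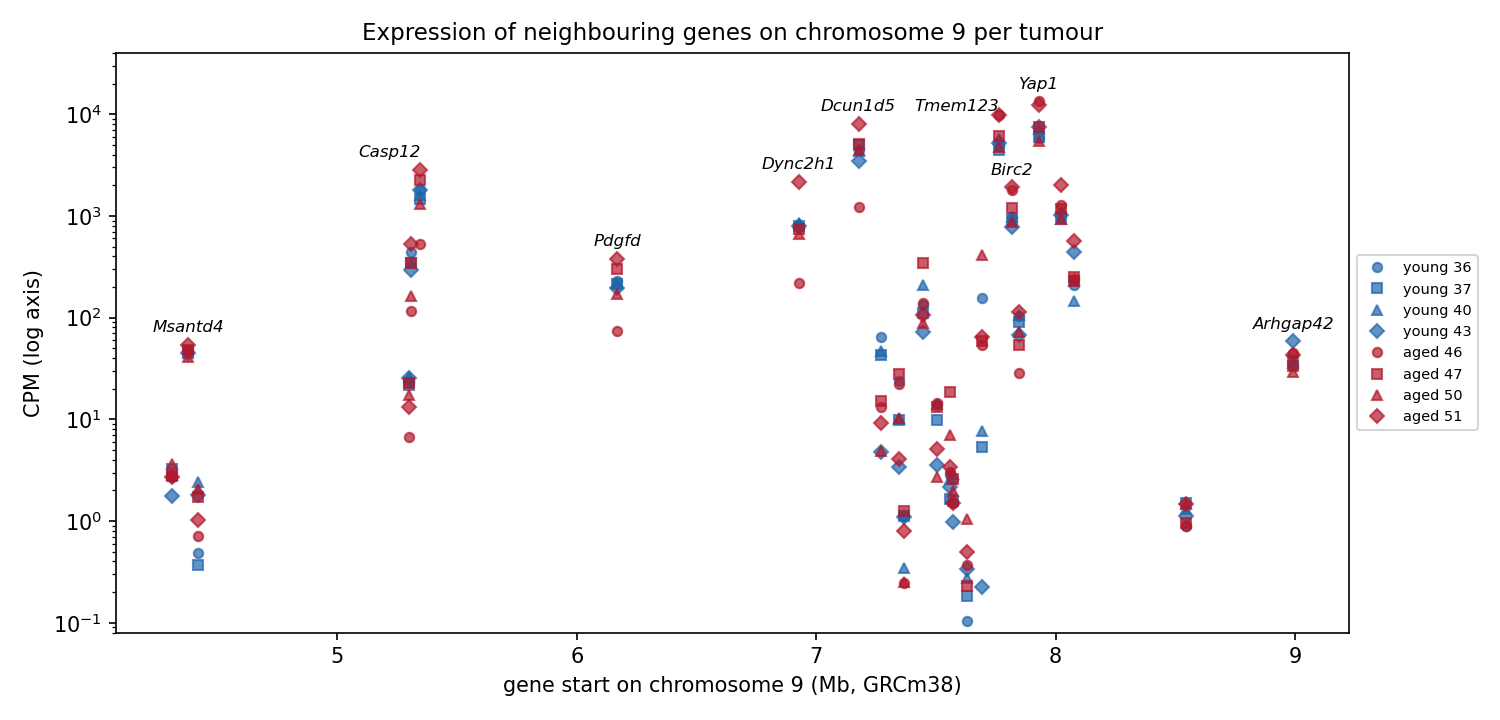
CPM on a log axis of each tested gene against its start on chromosome 9 (Mb, GRCm38), with red marks for the 4 aged and blue marks for the 4 young tumours. The Yap1 marks lie between 5440 and 13400 CPM, and the marks of Msantd4 on the left flank centre on 45.8 CPM.

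Transcripts typical of other tissues differed widely between tumours of the same group. The 4 tested seminal vesicle secretory genes averaged 12.65 log2 CPM in young 36 and 11.08 in aged 50, and at most 1.52 in the other 6 tumours. The filter left out Svs1, Svs3a, Svs3b and Svs6, which stood at 957 to 1775 CPM in young 36 but at 0.03 to 3.06 CPM in aged 50. Svs2, a semen coagulum protein, was the top gene of aged 50 with 1.79% of its fragments. The normal prostate secretory genes averaged 6.44 in aged 50, 6.16 in young 36, 5.35 in young 37 and -1.52 in young 43. Skeletal muscle markers averaged 3.96 in aged 51 and at most 1.5 in the others. T cell markers averaged 0.56 in aged 46, 1.04 in aged 51 and 0.74 in young 43, against 1.14 to 3.14 in the other 5. The first principal component of the 500 most variable genes, with 46.5% of the variance, ran from -55.5 in young 43 to 53.1 in aged 50. It did not part the host ages (exact two-sided permutation p = 0.46, 70 assignments, smallest possible 0.029), nor did the second (exact permutation p = 0.86) or the third component (exact permutation p = 0.97). Spearman correlations were 0.937 to 0.974 within the aged group, 0.964 to 0.982 within the young group and 0.934 to 0.987 between groups.

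**Figure D2:**
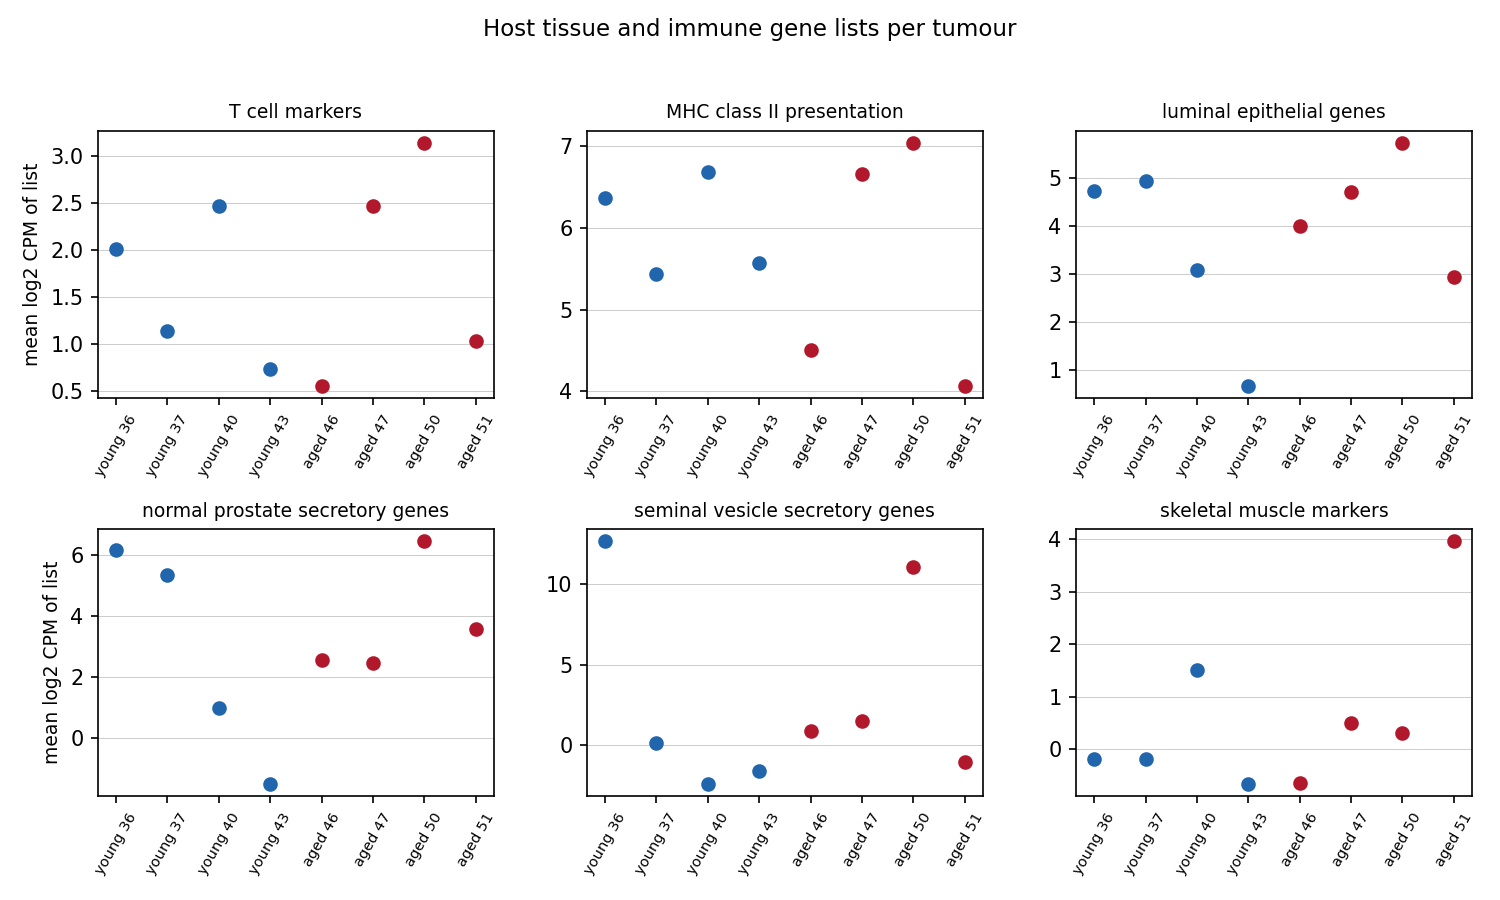
Mean log2 CPM of 6 gene lists in each of the 4 young (blue) and 4 aged (red) tumours, each point being 1 tumour. The 4 seminal vesicle secretory genes that passed the filter reach 12.65 in young 36 and 11.08 in aged 50, and skeletal muscle markers reach 3.96 in aged 51.

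Between the host ages, single genes had values that did not overlap, though none passed edgeR's test. Acp5, the tartrate-resistant acid phosphatase of osteoclasts and some macrophages, had 22.4 ± 4.08 CPM in aged tumours and 67.9 ± 16.2 CPM in young tumours (SD, n = 4 each), a log2 fold change of -1.60 ± 0.21 (SE). P4ha1, a prolyl hydroxylase that collagen folding needs, had 167 ± 14.1 and 276 ± 26.4 CPM, and Col6a3, a chain of collagen VI, 317 ± 65.4 and 636 ± 110 CPM. Vsig4, a complement receptor of tissue-resident macrophages, had 4.75 ± 1.64 CPM in aged and 0.688 ± 0.488 CPM in young tumours. Rbm3, a cold-inducible RNA-binding protein, had 599 ± 89.9 and 374 ± 26.2 CPM. For each of these 5 genes, all 4 aged tumours lay on the same side of all 4 young tumours. The naming rule required this of them, so it is no added support.

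Of 14575 genes tested, 0 passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.427 (Acp5). At an unadjusted p of 0.05, edgeR gave 728 genes (341 higher and 387 lower in aged tumours) where chance gives 729. DESeq2 called 43 genes (17 higher, 26 lower), limma voom called 9 (4 higher, 5 lower), and 7 were called by both. The 4 aged tumours did not overlap the 4 young tumours for 534 genes, or 3.66%, where chance gives 2.86%.

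The naming rule gave 10 leading genes, none past the edgeR threshold, and DESeq2 called all 10. Those higher in aged tumours were Olfr1033, an olfactory receptor gene (Entrez 258571, GRCm38 chromosome 2, 86020640 to 86044808), with a log2 fold change of 1.14 ± 0.19, and Akap12, a scaffold protein of kinase signalling (83397, chromosome 10, 4266329 to 4359471), with 0.94 ± 0.17. Wdr92 (103784, chromosome 11, 17211893 to 17235200) had 0.87 ± 0.16, Vsig4 (278180, chromosome X, 96247201 to 96293438) 2.79 ± 0.52 and Rbm3 (19652, chromosome X, 8138975 to 8145880) 0.68 ± 0.13. Those lower in aged tumours were Acp5 (11433, chromosome 9, 22126727 to 22135746), P4ha1 (18451, chromosome 10, 59323197 to 59373304) with -0.73 ± 0.11, and Col6a3 (12835, chromosome 1, 90766860 to 90844001) with -1.01 ± 0.19. Wnt6, a secreted Wnt ligand (22420, chromosome 1, 74754342 to 74785322), had -1.64 ± 0.28, and Flrt2, a membrane adhesion protein (399558, chromosome 12, 95692006 to 95785215), -0.59 ± 0.11, with young 43 (6.90 log2 CPM) above the other young tumours (6.63 to 6.65). The exons of Wdr92 overlap those of Ppp3r1 and Pno1 and the exons of Rbm3 and Acp5 those of a noncoding transcript on the opposite strand, and Olfr1033 belongs to a large gene family, so these 4 values are uncertain without the counting settings. Among the 10, voom called only Olfr1033, Akap12, Wdr92, Rbm3 and P4ha1. Calls by DESeq2 or voom are no independent support, as the same counts picked the genes. Of the 35 splits of the tumours into groups of 4, 8 gave at least the real 43 DESeq2 calls, the real split included.

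**Figure D3:**
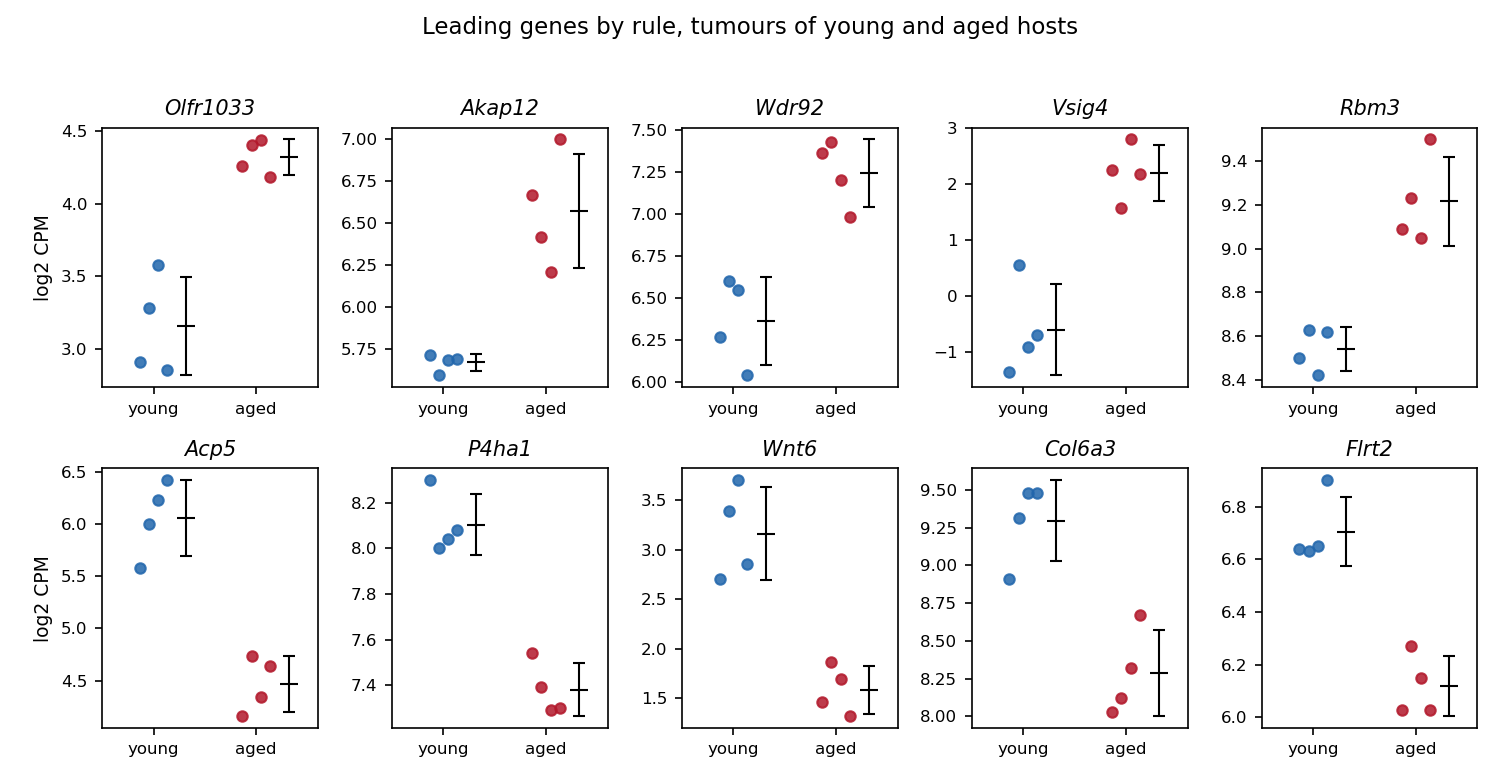
Log2 CPM of the 10 leading genes in 4 young (blue) and 4 aged (red) tumours, each point being 1 tumour, with the mean and SD in black. For every gene shown the groups do not overlap, as the naming rule required, with Acp5 at 4.47 ± 0.27 in aged and 6.05 ± 0.36 in young tumours.

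Gene lists were tested as groups, and 19 of 52 passed camera with its preset correlation, 7 upward and 12 downward in aged tumours. With an estimated correlation 0 of the 52 passed (smallest adjusted p = 0.26 with an estimated correlation), while 3 had an unadjusted p under 0.05. By fry 0 passed and 3 were under the unadjusted 0.05. By exact permutation of the list means 0 passed after adjustment (smallest adjusted p = 0.74), and only the angiogenesis list reached 0.029, the smallest exact p possible. As no list can go below that value, many lists would have to reach it together for any to pass after adjustment. The 0 by exact permutation was thus nearly fixed in advance and decides little. All list calls below are camera calls with the preset correlation and Benjamini-Hochberg adjustment over the 52 lists, and they rest on that preset. Some lists share members, so their calls are not independent of each other. Vegfa is in the angiogenesis, hypoxia and senescence-associated secretory lists, and P4ha1 in the hypoxia and matrix remodelling lists. Of the 35 ways to split the 8 tumours into 2 groups of 4, 18 gave at least 19 list calls, the real split included.

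All 14 interstitial collagens had lower values in aged tumours, with a list mean of 8.81 ± 0.44 log2 CPM in aged and 9.28 ± 0.24 in young tumours (SD, n = 4 each). The list fell by camera (adjusted p = 4.4e-06, and adjusted p = 0.58 with an estimated correlation). Aged 46 had the lowest mean (8.17, against 8.83 to 9.12 in the other aged tumours), and without it the mean log2 fold change went from -0.40 to -0.23. Col1a1 and Col3a1, the chains of the main fibrillar collagens, had log2 fold changes of -0.49 ± 0.28 and -0.46 ± 0.25, and Col5a3 had -0.76 ± 0.17. Over all genes tested 0 of the 14 passed by edgeR, and 2 passed adjusted over the list alone (Col5a3 and Col6a3), which DESeq2 called over all genes and voom did not. Fibroblast markers averaged 5.61 ± 0.53 and 5.83 ± 0.38, and this list did not pass (adjusted p = 0.051 by camera), though it did in 9 of 24 alternatives.

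The matrix glycoproteins fell by camera (12 of 16 lower, adjusted p = 0.0064, and adjusted p = 0.58 with an estimated correlation), with 0 members past the threshold over all genes by edgeR, DESeq2 or voom and 2 by edgeR adjusted over the list alone. These were the adhesion-modulating tenascin gene Tnc (-0.72 ± 0.20) and the proteoglycan gene Bgn (-0.54 ± 0.15), while Ctgf, a secreted growth factor of the same list, had 1.24 ± 0.40. Matrix remodelling enzymes and inhibitors fell by camera (11 of 16 lower, adjusted p = 0.011, and adjusted p = 0.66 with an estimated correlation), with 0 over all genes by edgeR and 2 adjusted over the list alone, P4ha1 and the gelatinase gene Mmp9 (-1.87 ± 0.39). DESeq2 called both over all genes, and voom P4ha1. The collagenase gene Mmp13, which lies within the chromosome 9 stretch, had -1.91 ± 0.67, with young 43 (2.24 log2 CPM) far below the other young tumours (5.44 to 6.07). TGF-beta target genes fell by camera (11 of 12 lower, adjusted p = 0.007, and adjusted p = 0.58 with an estimated correlation), with Tgfb3 at -0.46 ± 0.20 and 0 members past either threshold, over all genes (by edgeR, DESeq2 or voom) or adjusted over the list alone. Epithelial-mesenchymal transition genes fell by camera (10 of 12 lower, adjusted p = 0.016, and adjusted p = 0.58 with an estimated correlation), with 0 over all genes by edgeR and 1 adjusted over the list alone. That member was the transcription factor gene Snai1 (-0.76 ± 0.17), which DESeq2 called over all genes, and Twist1 had -0.31 ± 0.11 and Fn1 -0.54 ± 0.20. Basement membrane genes did not pass (adjusted p = 0.34 by camera), with Lama4 at -0.77 ± 0.20 and Lama5 at 0.56 ± 0.18. The glycoprotein call ended without aged 46 (adjusted p = 0.092 by camera), the remodelling call without aged 46 (0.14), aged 50 (0.13) or young 40 (0.081), and the transition call without aged 50 (0.21) or young 43 (0.074). Without young 40 the mean log2 fold change went from -0.19 to -0.10 for the glycoproteins, from -0.31 to -0.18 for the remodelling list and from -0.25 to -0.16 for the TGF-beta targets, and without aged 46 it went to -0.12 for the glycoproteins. Without aged 50 and young 36, an exclusion chosen after seeing the data, the remodelling call (0.094) and the transition call (0.21) ended, the latter also without aged 51 as well (0.2) and with a surrogate variable (0.11).

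Of 11 angiogenesis genes 10 had lower values, with a list mean of 3.65 ± 0.18 in aged and 4.16 ± 0.09 in young tumours and no overlap between the groups. This list fell by camera (adjusted p = 1.2e-05, and adjusted p = 0.26 with an estimated correlation). Vegfa, the main vascular growth factor, had a log2 fold change of -0.76 ± 0.22, its co-receptor gene Nrp1 -0.68 ± 0.16, the tip cell ligand gene Dll4 -0.71 ± 0.25 and Apln -0.70 ± 0.26. Over all genes 0 passed by edgeR, and 2 passed adjusted over the list alone (Vegfa and Nrp1), of which voom called Vegfa and DESeq2 called Nrp1 over all genes. Of 15 hypoxia and glycolysis genes 11 had lower values, and the list fell by camera (adjusted p = 4.6e-05, and adjusted p = 0.66 with an estimated correlation). The hexokinase gene Hk2 had -0.75 ± 0.19 (young 43 at 7.27 log2 CPM, the other young tumours at 6.82 to 6.86) and the glucose transporter gene Slc2a1 -0.58 ± 0.24, and 0 members passed over all genes by edgeR and 3 adjusted over the list alone (Vegfa, P4ha1 and Hk2). Over all genes voom called Vegfa and P4ha1, and DESeq2 P4ha1. Without aged 50 and young 36, the tumours high in seminal vesicle transcripts, the hypoxia call ended (adjusted p = 0.25 by camera, an exclusion chosen after seeing the data, and 0.86 without aged 51 as well). Its mean log2 fold change of -0.41 went to -0.26 without aged 50 alone and to -0.62 without aged 46. Markers of endothelial cells themselves did not pass (6 higher and 6 lower, adjusted p = 0.92 by camera, with mean and median fold changes of opposite sign), and Vwf had 0.95 ± 0.29.

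Interferon-stimulated genes had lower values in aged tumours throughout the list, with a wide spread between aged tumours. All 21 type I interferon response genes were lower, and the list fell by camera (adjusted p = 1e-06, and adjusted p = 0.79 with an estimated correlation). Its mean was 4.71 ± 0.95 in aged and 5.43 ± 0.39 in young tumours, with aged 46 at 3.7 and aged 51 at 4.27. Aged 50, at 5.89, lay above every young tumour (4.87 to 5.71). Its mean log2 fold change of -0.51 went to -0.26 without aged 46 and to -1.04 without aged 50. Bst2, a virus-tethering membrane protein, had a log2 fold change of -0.70 ± 0.32 and Oas1a -0.87 ± 0.51. The interferon gamma response fell by camera (12 of 15 lower, adjusted p = 0.0054, and adjusted p = 0.79 with an estimated correlation), with the chemokine gene Cxcl10 at -0.91 ± 0.39. MHC class I presentation fell by camera (11 of 13 lower, adjusted p = 0.034, and adjusted p = 0.79 with an estimated correlation), with B2m at -0.22 ± 0.41. In these 3 lists 0 members passed over all genes by edgeR, DESeq2 or voom, and 0 adjusted over the list alone. The estimated correlation between members was 0.93, 0.88 and 0.84 in turn, so the members of a list are not independent evidence. The exact permutation p of the list mean was 0.26, 0.4 and 0.46. Aged 46 and aged 51, the aged tumours lowest in these lists, were also low in T cell markers (0.56 and 1.04) and in MHC class II presentation (4.51 and 4.07, against 5.44 to 7.04 in the other 6). The interferon gamma call ended without aged 46 (adjusted p = 0.2 by camera) or aged 51 (0.14), and the MHC class I call without aged 46 (0.86), aged 51 (0.25), young 36 (0.082) or young 40 (0.14). Under voom both ended (0.94 with a mean log2 fold change of 0.08, and 0.74 with -0.02), and the MHC class I call also with library size scaling (0.052) and upper quartile factors (0.054). The mean log2 fold change of the interferon gamma list, -0.24, went to 0.01 without aged 46 or aged 51, to -0.03 without young 40, to -0.74 without aged 50, to -0.39 without aged 47 and to -0.38 without young 37. That of the MHC class I list, -0.16, went to 0.07 without aged 46, to 0.00 without aged 51, to -0.06 without young 40, to -0.56 without aged 50 and to -0.27 without aged 47 or young 43.

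Among immune cells, macrophage genes linked to alternative activation were higher in aged tumours. Of 10 such genes 9 had higher values, with a mean of 3.04 ± 0.60 in aged and 2.04 ± 0.56 in young tumours, and the list rose by camera (adjusted p = 0.00064, and adjusted p = 0.58 with an estimated correlation). Over all genes 0 passed by edgeR, while DESeq2 called Chil3 and Cd163, and 4 passed by edgeR adjusted over the list alone. These were the haemoglobin scavenger receptor gene Cd163 (1.89 ± 0.44), the chitinase-like gene Chil3 (1.93 ± 0.42), the eotaxin gene Ccl24 (2.20 ± 0.70) and Retnla (3.37 ± 1.16), with Retnla at -2.62 log2 CPM in aged 46 and 3.78 in aged 50. General macrophage markers did not pass (11 of 14 lower, adjusted p = 0.051 by camera), at 7.25 ± 0.36 and 7.38 ± 0.19, with 0 members over all genes by edgeR and 1 adjusted over the list alone (Cd163, which DESeq2 called over all genes). Of the remaining immune lists none passed by camera. The adjusted p was 0.4 for T cell markers (13 of 14 higher), 0.76 for cytotoxic and NK cell markers, 0.9 for B cell markers, 0.12 for plasma cell markers and 0.14 for neutrophil markers. Of the neutrophil markers 0 passed over all genes by edgeR and 4 adjusted over the list alone. Cxcr2, Retnlg and Mmp8 were higher in aged tumours, and Mmp9, called by DESeq2 over all genes, was lower. The neutrophil list averaged 4.23 in aged 47 and 2.2 to 2.88 in the other aged tumours. The adjusted p by camera was 0.64 for dendritic cell markers, 0.9 for mast cell markers, 0.12 for MHC class II presentation, 0.093 for chemokines, 0.9 for complement genes and 0.63 for immune checkpoint and regulatory T cell genes. Cd8a, the co-receptor of cytotoxic T cells, had a log2 fold change of 0.88 ± 0.63, Cd274, which encodes the ligand PD-L1, -0.10 ± 0.41, and the B cell chemokine gene Cxcl13 1.83 ± 0.72. For the cytotoxic, B cell, dendritic, mast cell, checkpoint and complement lists the sign of the camera test differed from that of the mean or median fold change.

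Androgen response genes and circadian clock genes were higher in aged tumours as lists. Of 12 androgen response genes 8 had higher values, and the list rose by camera (adjusted p = 0.016, and adjusted p = 0.58 with an estimated correlation), from 4.21 ± 0.53 in young to 4.79 ± 0.28 in aged tumours. Its leading members were Herc3 (0.82 ± 0.20), Tsc22d3 (1.55 ± 0.50), Fkbp5 (0.77 ± 0.29) and Zbtb16 (1.80 ± 0.80), of which the last 3 are also known targets of the glucocorticoid receptor. These 3 were highest in aged 51 (Tsc22d3 at 8.02 log2 CPM, against 5.66 to 6.46 in the other aged tumours), the tumour with skeletal muscle markers at 3.96 and the highest adipocyte markers (3.74). Over all genes 0 passed by edgeR, DESeq2 or voom, and 1 passed by edgeR adjusted over the list alone (Herc3). The androgen call ended without aged 50 (adjusted p = 0.051 by camera) or young 43 (0.088), the tumours with the highest and lowest level of normal prostate secretory genes. Of 14 circadian clock genes 12 had higher values, and the list rose by camera (adjusted p = 0.0054, and adjusted p = 0.58 with an estimated correlation). Per1 had 0.93 ± 0.35, Tef 0.75 ± 0.23 and Nr1d2 0.42 ± 0.16, while the repressor gene Bhlhe41 had -0.78 ± 0.23, and 0 members passed over all genes by edgeR, DESeq2 or voom and 0 adjusted over the list alone. Per1 too was highest in aged 51 (7.31 log2 CPM, against 5.67 to 6.52 in the other aged tumours). Without aged 50, young 36 and aged 51, an exclusion chosen after seeing the data, the clock call ended (adjusted p = 0.068 by camera) and its mean log2 fold change went from 0.33 to 0.19.

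The senescence-associated secretory genes fell by camera (10 of 17 lower, adjusted p = 0.0054, and adjusted p = 0.58 with an estimated correlation), with 0 over all genes by edgeR and 3 adjusted over the list alone, while voom called Vegfa over all genes. The exact permutation p of the list mean was 0.26. The 3 members were the macrophage growth factor gene Csf1 (-0.61 ± 0.15), the cytokine gene Lif (-0.76 ± 0.21) and Vegfa, and the call ended without aged 51 (adjusted p = 0.073 by camera), or without aged 50, young 36 and aged 51 (0.33, chosen after seeing the data). The mean log2 fold change of -0.24 went to -0.15 without aged 51 and to -0.13 without young 40. Il6 had -0.58 ± 0.53 and Il1b -1.49 ± 0.66. Cell cycle inhibitors and senescence genes did not pass (adjusted p = 0.41 by camera, with the signs of mean and median differing), with Cdkn2a at -0.07 ± 0.19, Cdkn1a at -0.11 ± 0.20 and Cdkn1c at 1.36 ± 0.54. Neither mitotic proliferation genes (adjusted p = 0.76 by camera) nor DNA replication genes (0.085) passed, and the proliferation marker Mki67 had -0.05 ± 0.27. The adjusted p was 0.92 for p53 target genes, 0.49 for oxidative stress response genes and 0.76 for Myc and ribosome biogenesis genes, and in the p53 and Myc lists the signs of the test, mean and median differed.

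Among stress, metabolic, epithelial and adipocyte lists, 5 passed, with mean log2 fold changes of -0.39 (heat shock), 0.10 (oxidative phosphorylation), 0.60 (luminal), 0.91 (basal) and 0.62 (adipocyte). Heat shock genes fell by camera (8 of 10 lower, adjusted p = 0.03, and adjusted p = 0.66 with an estimated correlation), with the chaperone genes Hsph1 at -0.86 ± 0.26 and Hspa1a, which has a near-identical copy in Hspa1b, at -1.36 ± 0.69. Oxidative phosphorylation genes rose by camera (17 of 19 higher, adjusted p = 0.027, and adjusted p = 0.79 with an estimated correlation) by a median of 0.10, with the complex I gene Ndufs3 at 0.20 ± 0.09. Luminal epithelial genes rose by camera (11 of 12 higher, adjusted p = 0.025, and adjusted p = 0.79 with an estimated correlation), although the keratin genes Krt8 and Krt18 had -0.34 ± 0.56 and 0.83 ± 0.88. Basal epithelial genes rose by camera (10 of 10 higher, adjusted p = 0.027, and adjusted p = 0.79 with an estimated correlation), with Krt17 at 1.57 ± 0.85. Adipocyte markers rose by camera (9 of 9 higher, adjusted p = 0.031, and adjusted p = 0.79 with an estimated correlation), with Fabp4 at 0.85 ± 0.85. In these 5 lists 0 members passed over all genes by edgeR, and 0 adjusted over the list alone, while voom called Hsph1 over all genes. Luminal genes averaged 5.72 in aged 50 and 0.68 in young 43, the tumours that stood highest and lowest in normal prostate secretory genes. The luminal call ended without aged 46 (adjusted p = 0.056 by camera), aged 47 (0.077), aged 50 (0.28, mean log2 fold change -0.06), young 40 (0.055) or young 43 (0.84, mean 0.23), and its mean was 1.04 without young 37. The basal call ended without aged 46 (0.051), aged 47 (0.3, mean 0.51), aged 50 (0.17) or young 43 (0.38), and its mean was 1.37 without young 40. The adipocyte call ended without aged 47 (0.051), aged 50 (0.15), aged 51 (0.25, mean 0.20) or young 36 (0.74, mean 0.28), and its mean was 1.10 without young 43. The oxidative phosphorylation call ended without aged 46 (0.36), aged 47 (0.055), young 40 (0.067) or young 43 (0.36), with a mean of 0.06 without aged 46 or young 43. The heat shock call ended without aged 47 (0.099), aged 50 (0.17), young 36 (0.11) or young 37 (0.082). Without aged 50 and young 36, chosen after seeing the data, the heat shock (0.38), basal (0.1) and adipocyte calls (0.75) ended. Without aged 51 as well, heat shock stood at 0.52 and adipocyte markers passed in the opposite direction (mean log2 fold change -0.60, adjusted p = 0.011 by camera). A surrogate variable ended the adipocyte (0.086), luminal (0.14), basal (0.19) and heat shock calls (0.051), a mean of at least 5 CPM the adipocyte (0.077) and basal calls (0.34), and voom (0.081) or no filter (0.071) the oxidative phosphorylation call.

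Other lists did not pass by camera. The adjusted p was 0.051 for endoplasmic reticulum stress genes (11 of 14 lower), 0.056 for Notch pathway genes (9 of 11 lower), 0.059 for cholesterol and fatty acid synthesis genes (15 of 15 lower), 0.16 for immediate early genes, 0.41 for ribosomal protein genes and 0.55 for Wnt target genes. Among markers of other tissues it was 0.073 for smooth muscle and pericyte markers, 0.085 for skeletal muscle markers, 0.18 for normal prostate secretory genes, 0.63 for lymphatic endothelial markers (0 members over all genes by edgeR, DESeq2 or voom and 1, Lyve1, by edgeR adjusted over the list alone), 0.082 for neuroendocrine genes and 0.16 for Schwann cell markers. For the smooth muscle and normal prostate lists the mean and median fold changes had opposite signs. Seminal vesicle secretory genes and erythroid genes had 4 tested members each, too few for camera, and the exact permutation p of their means was 0.69 and 0.31.

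**Figure D4:**
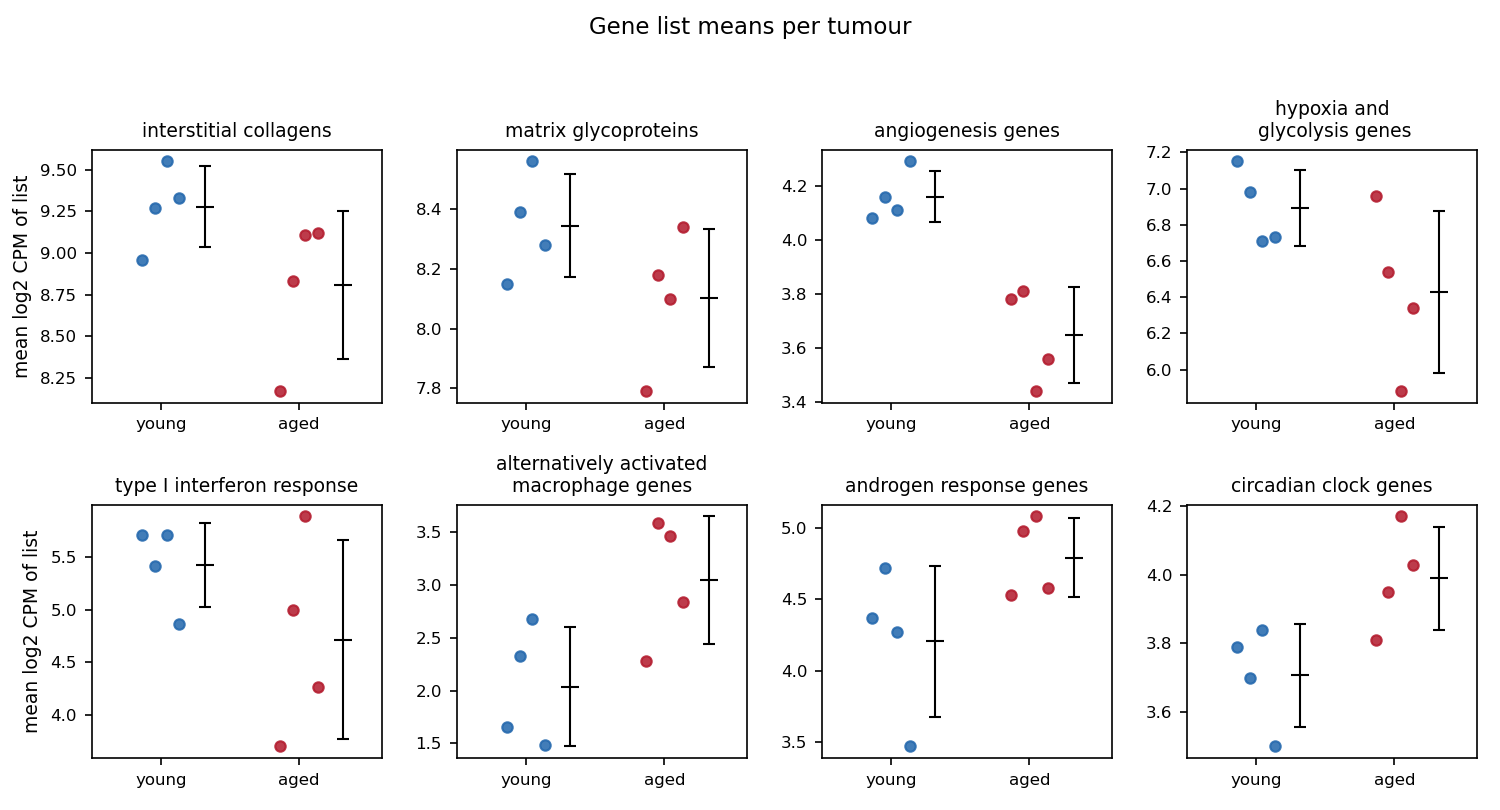
Mean log2 CPM of 8 gene lists in 4 young (blue) and 4 aged (red) tumours, each point being 1 tumour, with the mean and SD in black and an axis range of its own for each list. Angiogenesis genes lie at 3.65 ± 0.18 in aged and 4.16 ± 0.09 in young tumours without overlap, and type I interferon response genes at 4.71 ± 0.95 and 5.43 ± 0.39 with overlap.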

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

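The tests of host gland transcripts, of fibroblast markers and of the estimated correlation, and the splits for DESeq2 and voom, were chosen only after the result was seen.

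Within the 4 tumours of a group, 5 of 258 groups of values held a tumour far from the other 3, where chance gives about 1 in 20 groups, or 12.9. Erythroid genes averaged 4.5 log2 CPM in aged 46 and 3.60 to 3.66 in the other aged tumours. The other 4 concern young 43. Its oxidative stress response genes averaged 6.35 (other young tumours 6.01 to 6.03), Flrt2 stood at 6.90 (6.63 to 6.65), Hk2 at 7.27 (6.82 to 6.86) and Mmp13 at 2.24 (5.44 to 6.07).

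Secretory transcripts typical of prostate and seminal vesicle were abundant in some tumours of each group. Host age alone cannot account for differences among the young tumours, whose normal prostate secretory means span 7.68 (4 in the aged tumours). The bound on this span was set after the values were seen, and a spread within a group does not test for a shift between groups. In young 36 8 of 8 seminal vesicle genes stood at 100 or more times their highest level in the tumours other than aged 50, but the tumour was picked for these genes, so seminal vesicle tissue there stays open. In aged 50 only 2 of the 7 genes other than Svs2 reached 0.1 of the level that its Svs2 needs at the proportions of young 36 (Svs1 0.03 of 3580 CPM), which argues against tissue of that make-up, and an earlier form of this test, whether aged 50 and young 36 were the highest pair, had given 7 of 8. Adjacent prostate in the sampled tissue stays open, as the 12 prostate genes had a median pairwise Spearman correlation of 0.48.

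All 14 interstitial collagens had lower values in aged tumours. Dilution by host gland stays open. The median log2 fold change of the collagens was -0.35 with the secretory score as a covariate and -0.36 without it. This cannot decide, because host gland transcripts differed little between the groups relative to their spread, so the age term had little room to move. The exact permutation p was 0.66 for the mean of the normal prostate secretory genes and 0.69 for the seminal vesicle secretory genes. Fewer fibroblasts cannot be told apart from a lower output per cell, because fibroblast markers differed by -0.23 (exact permutation p = 0.49) and collagens by -0.47 (exact permutation p = 0.11). Bulk counts also do not show which cells, injected or host, made the collagen transcripts. A lower output of collagen-processing genes other than those already seen also stays open (14 of 16 lower, difference -0.10, exact permutation p = 0.43). Host age itself remains possible but is not shown. The collagen mean did not part the host ages (exact permutation p = 0.11), so chance is not excluded either.

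Counts of calls were set against all 35 splits of the 8 tumours into 2 groups of 4. For edgeR genes past the threshold, in total, higher and lower, the real count of 0 fixes the outcome (35 of 35 splits give at least 0, highest other 3, 0 and 3), so nothing follows from these. Chance cannot be excluded for the other counts. With the real split counted among them, 12 splits gave at least the real 728 unadjusted genes (highest other 2852), 18 at least 19 lists (highest other 32), 8 at least 43 DESeq2 genes (highest other 924) and 2, so 1 other split, at least 9 voom genes (highest other 32). Splits that put aged 46, aged 51 and young 43 together gave up to 2852 unadjusted genes, which points to a structure of the tumours other than host age. With the correlation estimated per list (median 0.27 in the passed lists) 0 list calls were left.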

How the results depend on the processing

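Excluding tumours with transcripts of other tissues, permuting list means and other prior counts were chosen only after the result was seen. By edgeR 0 genes passed under every scaling, filter, covariate and threshold tried and with each tumour left out (0 to 0; 728 at an unadjusted p under 0.05). DESeq2 called 43 (17 higher, 26 lower) and voom 9 (4 higher, 5 lower), and the cause was not tested. List calls numbered 19, and 17 to 25 with each tumour left out, 29 at an adjusted p under 0.1, and 0 with an estimated correlation, 0 by fry and 0 by exact permutation of list means. The count by exact permutation was nearly fixed in advance by the smallest exact p possible. They numbered 18 or 19 under other scalings, 28 with voom (16 shared), 26 with the secretory score (19 shared), 24 with a surrogate variable (14 shared), 21 without aged 50 and young 36 (13 shared) and 17 without aged 51 as well (14 shared). The camera test turned upward for cytotoxic and NK cell markers (mean log2 fold change 0.39, from 0.11) and B cell markers (0.78, from 0.49) under voom. For adipocyte markers (0.62) it turned downward without aged 50 and young 36 (0.16) and without aged 51 as well (-0.60, adjusted p = 0.011, a call in the opposite direction, with 0.00021 to 0.89 over all alternatives), and the cause was not tested. Calls that held while the mean log2 fold change moved by over 1.5 times were those of type I interferon (-0.92), interferon gamma (-0.81) and MHC class I (-0.54) with a surrogate variable, interferon gamma (-0.38), MHC class I (-0.32) and adipocyte (1.03) with the secretory score, adipocyte (1.61), basal (1.47) and senescence secretory lists (-0.15) with voom, the last with at least 5 CPM (-0.39) and interferon gamma without a filter (-0.13), beside those given for left-out tumours. Without aged 50 and young 36 they included type I interferon (-0.95), interferon gamma (-0.77), MHC class I (-0.52) and luminal genes (0.24). Without aged 51 as well they included interstitial collagens (-0.84), matrix glycoproteins (-0.41) and oxidative phosphorylation (0.18). In that setting the 3 interferon and MHC class I lists also moved, to -0.89, -0.5 and -0.39. The exact p of the first component was 0.46, 0.71 with all genes, 0.49 and 0.51 with prior counts of 0.5 and 5, and 0.37 to 0.91 with each tumour left out. Of 3229 comparisons over 155 named genes, 0 reversed, 23 became calls and 51 changed sign without a call. Lists not called became calls in up to 10 of 24 alternatives (endoplasmic reticulum stress and Notch lists 10, fibroblast and smooth muscle lists 9, macrophage, chemokine and cholesterol lists 7). No paired analysis was possible because the groups share no numbers. The gene tests use no pseudocount, while camera and the levels use a prior count of 2, and list calls numbered 19 with 0.5 and 22 with 5 (19 shared each, with macrophage, fibroblast and endoplasmic reticulum stress lists added at 5), with 0 by exact permutation at each. Depth limits single levels below 0.084 to 0.111 CPM (3 fragments).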

Other observations

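The clock arm test was chosen only after the result was seen, and the gene sets of the other tests were chosen after the leading genes, but before the values of their members, were seen.

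Genes induced by glucocorticoids had higher values in aged tumours beyond those of the androgen list. Of 13 further targets 12 were higher, with means of 4.66 ± 0.53 log2 CPM in aged and 4.07 ± 0.23 in young tumours (SD, n = 4 each). Klf9, a transcription factor, had a log2 fold change of 1.03 ± 0.30 (SE), Pdk4, which restrains pyruvate oxidation, 2.80 ± 0.96, and Fam107a 2.50 ± 0.86. None of the 13 passed over all genes by edgeR, DESeq2 or voom, and the exact permutation p of the mean was 0.11. These 3 genes were highest in aged 51 (Pdk4 4.06 log2 CPM, Fam107a 1.91, Klf9 6.05), the tumour with skeletal muscle markers at 3.96 and the highest adipocyte markers (3.74). In aged 46 Pdk4 (-1.24) and Fam107a (-2.36) were as low as in the lowest young tumour.

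Genes of osteoclasts and related macrophages had lower values beside Acp5. Of 8 further genes 7 were lower, with means of 3.32 ± 0.27 in aged and 3.87 ± 0.28 in young tumours. The protease gene Ctsk had -1.29 ± 0.34 and the proton pump subunit gene Atp6v0d2 -1.36 ± 0.40, while Gpnmb had 0.97 ± 0.31, and the exact permutation p of the mean was 0.057.

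The hypotheses below were tested on genes other than those that prompted them, except that of the clock, whose test used members of the same list. A candidate explanation for Tsc22d3, Fkbp5, Zbtb16 and Per1 is a stronger glucocorticoid signal in aged hosts, which the exact permutation p of 0.11 leaves open. Another hour of harvest may account for the clock genes, for which the Dbp and Arntl arms, which run against each other, would move apart. Instead both were higher (0.29, exact permutation p = 0.23, and 0.34, exact permutation p = 0.086), with a difference of -0.04 (exact permutation p = 0.86). As first written, the bound against this explanation, both arms higher and no difference past 0.05, is met, and a stricter bound was put in its place after the result was seen. The explanation is left open only because neither arm is higher beyond its spread. A loss of osteoclast-like cells may underlie Acp5 and Mmp9 (exact permutation p = 0.057). Resident macrophages may underlie Vsig4 and Cd163, and 5 of 7 other such genes were higher, F13a1 at 1.03 ± 0.41 (exact permutation p = 0.49). A lower tissue temperature may raise Rbm3, and the other cold-inducible gene Cirbp had 0.77 ± 0.24 (exact permutation p = 0.086). Adjusted over these sets and the collagen-processing set, the exact permutation p was 0.18 to 0.49, so none of these hypotheses is shown.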
